A study of Mus musculus with 9 samples.

How the data were processed

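Liver RNA of 9 male C57BL/6 mice was sequenced, 4 wild type and 5 labelled Msr1-/-, after 16 weeks on a diet rich in fat and cholesterol. Groups and animal numbers came from the sample titles, and each animal gave 1 library. The libraries were made with a TruSeq RNA kit, per the labels' protocols, which state no strand setting for the counting. STAR, HTSeq, DESeq2 and the build mm10 are named in the submitters' processing notes, with no versions. The authors deposited 1 table with a signal per gene and liver, gene read counts divided by a size factor, of 17442 genes. Each value in a liver was a whole multiple of 1 step within a tolerance of 0.01 reads (100% of values), so whole reads were recovered by dividing by that step. They came to 15006773 to 18238932 reads per liver, and the smallest gene total over the 9 livers was 10 reads. These depths cover counting error only, and the spread between animals sets the precision of the comparisons.

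Values were taken as log2(value + 1), and genes with a mean of 10 or more over the 9 livers were tested, 12937 in all. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend in the empirical Bayes step, genotype as the only term and Benjamini-Hochberg adjusted p under 0.05. The fold changes, standard errors and adjusted p values of single genes are limma's. Msr1 was tested by a two-sided exact permutation test of mean log2 values. Gene lists with 3 or more tested genes, 35 of 38, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p values of lists are over the 35 lists. Coordinates came from the GENCODE M21 annotation of GRCm38, the assembly of mm10, matched by symbol for 16881 genes and by an older symbol for 263, with 298 unmatched.

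The design, the 38 gene lists and the rule for named genes were fixed before the data were examined. The rule names Msr1, the 10 largest and 10 smallest log2 fold changes among called genes whose genotypes do not overlap, the 8 genes of smallest p among called genes with a mean of 100 or more, up to 4 genes of smallest p in each list, and always Cd36, Marco, Tnf, Ccl2, Il1b, Il6, Adgre1, Clec4f, Trem2, Col1a1, Acta2, Pparg, Cyp7a1 and Nnt. Features named Gm with a number, ending in Rik or without a symbol are counted and not named under the first parts of the rule. A gene without a read in every liver of a genotype is given against a floor of 3 reads per liver.

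Alternatives planned were pseudocounts of 0.5 and 5, no filter and a mean of 50 or more, TMM and quantile scaling, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, array weights, the animal number as a block, and each liver left out in turn. Pairing was not used in the main test, since genotype was set as the only term before the data were examined. The deviations of same-numbered animals from their genotype means correlated at 0.025, -0.077, -0.1 and 0.22, and animals of different numbers were not compared. Added after seeing the data were edgeR and DESeq2 without wild type 3, and all genes of chromosome 8 left out. On simulated counts with the real means, dispersions and depths (12937 genes, 100 changed 2-fold and 100 changed 4-fold), limma recovered 51% and 87% of them, and 7.38% of 149 calls were false. In a simulation with 1 list raised 1.5-fold, camera called that list and 0 of 33 lists that share no gene with it. Each gene was drawn independently there, so this does not show how camera behaves on lists whose genes move together. No pair of libraries was a duplicate, since the lowest chi-square per degree of freedom between 2 livers was 19.7. All columns of the table matched a labelled animal.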

Results

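RNA from the livers of 9 male mice was measured by RNA sequencing, 4 of them wild type and 5 labelled Msr1-/-. Msr1 encodes macrophage scavenger receptor 1, a cell surface receptor through which macrophages take up modified lipoproteins. All mice had eaten a diet rich in fat and cholesterol for 16 weeks, a diet under which mice develop fatty liver disease. The deposited table gave size-factor-normalised read counts for 17442 genes, from which between 15006773 and 18238932 reads per liver were recovered. A gene total over the 9 livers of at least 10 reads was found for each listed gene, and 12937 genes had a mean of 10 or more and were tested. The comparison asked how the liver transcriptome on this diet differs without the receptor. Values below are normalised read counts as mean ± SD over n = 4 wild-type livers and n = 5 livers labelled Msr1-/-, and fold changes are on the log2(value + 1) scale, which understates the change of low genes.

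One wild-type liver stood apart from the rest. Wild type 3 scored -88.74 on the first principal component, which held 41% of the variance, while the other 8 livers scored between -8.3 and 27.61. The correlations of wild type 3 with the other livers lay between 0.895 and 0.933 across genes. The median correlation of each other liver with the rest was 0.964 or more. In wild type 3 the macrophage gene Trem2 stood at 178.1 and the collagen gene Col1a1 at 563.3, against 27.1 ± 6.5 and 79.3 ± 46.6 in the other 3 wild-type livers. Its read total of 16987095 lay within the range of the other livers. The comparison was therefore also run without wild type 3, a rerun planned for each liver in turn.

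**Figure D1:**
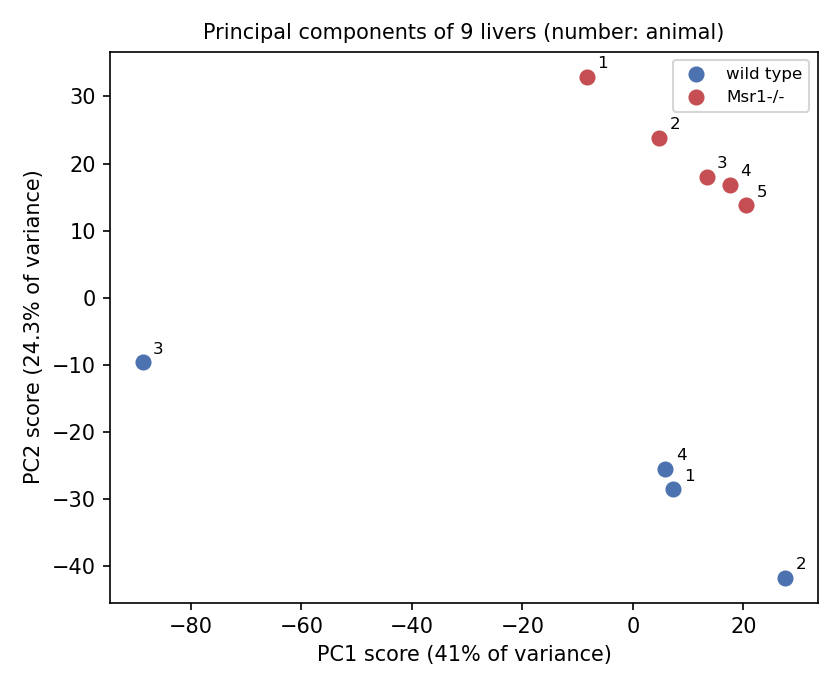
Scores of the 9 livers on the first component (41% of the variance) and the second (24.3%), with points coloured by genotype and numbered by animal. Wild type 3 lies at -88.74 on the first component, and the second separates the livers labelled Msr1-/- (13.79 to 32.97) from the wild-type livers (-41.75 to -9.62).

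Msr1 reads were present in each of the 9 livers. Msr1 (chromosome 8, 39581685 to 39642673 in mm10, minus strand) stood at 175.4 ± 23.0 (SD, n = 5) in the livers labelled Msr1-/-, between 152.7 and 209.1, and at 278.0 ± 124.7 (SD, n = 4) in wild type, between 194.5 and 460.5. The mean log2 difference was -0.58, a 1.49-fold lower level, with a two-sided exact permutation p of 0.0476, the smallest p that the splits of 9 livers allow being 0.0159. Without wild type 3 the wild-type mean was 217.2 ± 33.4 (n = 3), the difference was -0.31 and the exact permutation p was 0.107, where 56 splits allow 0.0357. The call was also lost on leaving out any other liver but Msr1-/- 3, with exact permutation p between 0.0714 and 0.107. The fixed lists of Kupffer cell and lipid-associated macrophage genes had median log2 fold changes of -0.76 and -1.21. Without wild type 3 both medians were -0.62. The fall of Msr1 was thus smaller than these medians, with and without wild type 3. Gene totals do not show which exons the reads came from, so the level of Msr1 does not check the labels clearly. Every direction below rests on the genotype as labelled.

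At an adjusted p under 0.05 in limma, 86 genes were higher and 91 lower in the livers labelled Msr1-/-, of which 46 and 62 differed by more than 2-fold. Among the genes that the naming rule covers, whose genotypes do not overlap, the largest increase was in Cyp2b9, a cytochrome P450 gene, which went from 3.6 ± 2.0 to 141.8 ± 71.2 (28.5-fold, limma adjusted p = 0.00383). Acot3, a peroxisomal acyl-CoA thioesterase gene, rose 25.2-fold, from 18.3 ± 14.6 to 329.5 ± 98.2, a log2 difference of 4.65 that was 3.78 without wild type 2. Hao2, a peroxisomal hydroxyacid oxidase gene, rose 10.6-fold, from 2.6 ± 0.5 to 41.4 ± 19.3. Lrtm1 rose 8.19-fold (4.78-fold without wild type 3), the cytochrome P450 gene Cyp2c29 6.11-fold, and Sema5b 5.87-fold. The angiotensin-(1-7) receptor gene Mas1 rose 5.84-fold, Cndp1 4.66-fold, the tropomyosin gene Tpm2 4.49-fold and the fatty acid omega-hydroxylase gene Cyp4a10 4.24-fold. Moxd1 fell from 1133 ± 1016 to 1.1 ± 1.5, and the neutrophil protease gene Prtn3 from 43.6 ± 42.5 to 0.6 ± 0.9. The wild-type mean of Moxd1 was 1503 ± 852 without wild type 3, whose value was 21.97. The log2 difference of Prtn3 was -4.23, and -3.63 without wild type 2. Gldn had no read in the 5 livers labelled Msr1-/- and 26.6 ± 33.8 in wild type, at least 8.65-fold lower against a floor of 3 reads per liver. Wild type 3 held 76.88 of Gldn, and without it the wild-type mean was 9.8 ± 5.0, under the mean of 10 needed for a test. The trefoil peptide gene Tff3 fell 15.6-fold, Dnaic1 7.87-fold, and Fgl1, which encodes a protein secreted by hepatocytes, and Hapln4 6.57-fold and 6.43-fold. The fatty acid binding protein gene Fabp5 fell 5.99-fold, the lysophosphatidic acid receptor gene Lpar2 5.32-fold and the asparagine synthetase gene Asns 4.70-fold. Among genes with a mean of 100 or more, the smallest p values belonged to Zfp868 (3.49-fold higher, from 96.0 ± 20.2 to 333.5 ± 31.9, limma adjusted p = 0.000485), Mtmr7 (3.27-fold higher), Pnldc1 (3.36-fold higher), Sema5b, Cebpe (2.09-fold higher), Impg2 (2.24-fold higher), Rpl30 (1.66-fold lower) and Fabp5. The genotypes did not overlap in 176 of the 177 called genes and in 7.29% of all tested genes, where chance gives 1.59%.

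The number of called genes changed with the liver left out and with the tool. Without wild type 3, limma called 332 genes higher and 297 lower, 174 of the 177 among them. On all 9 livers, DESeq2 called 307 higher and 466 lower, limma with array weights 277 and 254, and edgeR 74 and 111. On leaving out 1 liver labelled Msr1-/-, the total fell to between 36 (without Msr1-/- 2) and 65 (without Msr1-/- 5), with 46, 50 and 47 genes without Msr1-/- 1, 3 and 4. It was 87 without wild type 1, 64 without wild type 2 and 192 without wild type 4. Of 46 called genes named here, 18 stayed under an adjusted p of 0.05 in limma in all 9 such fits. These were Cyp2b9, Acot3, Hao2, Sema5b, Tpm2, Moxd1, Tff3, Hapln4, Fabp5, Lpar2, Zfp868, Mtmr7, Pnldc1, Cebpe, Impg2, Rpl30, Sox9 and Acot4. The direction of each of the 46 held. Mas1 lost its call only without Msr1-/- 2 (limma adjusted p = 0.0538). Cyp2c29 lost it without Msr1-/- 1, 2 or 4 or wild type 2, and Cyp4a10 without Msr1-/- 1 to 4 or wild type 1, with adjusted p up to 0.0657 and 0.0715. Lrtm1, Cndp1, Prtn3 and Fgl1 lost theirs without any 1 of the livers labelled Msr1-/- or wild type 1 or 2 (limma adjusted p up to 0.0886, 0.113, 0.0947 and 0.0991). Gldn did so without any 1 of the livers labelled Msr1-/- or wild type 1 (limma adjusted p up to 0.0753). Dnaic1 and Asns did so without Msr1-/- 1 to 4 or wild type 1 or 2 (limma adjusted p up to 0.0924 and 0.0718). Cyp2b9, Cyp2c29, Cyp4a10, Acot3, Acot4, Saa1, Saa2, Igkc and the ribosomal protein genes have close relatives or pseudogenes, so their counts carry some uncertainty about which copy the reads came from.

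**Figure D2:**
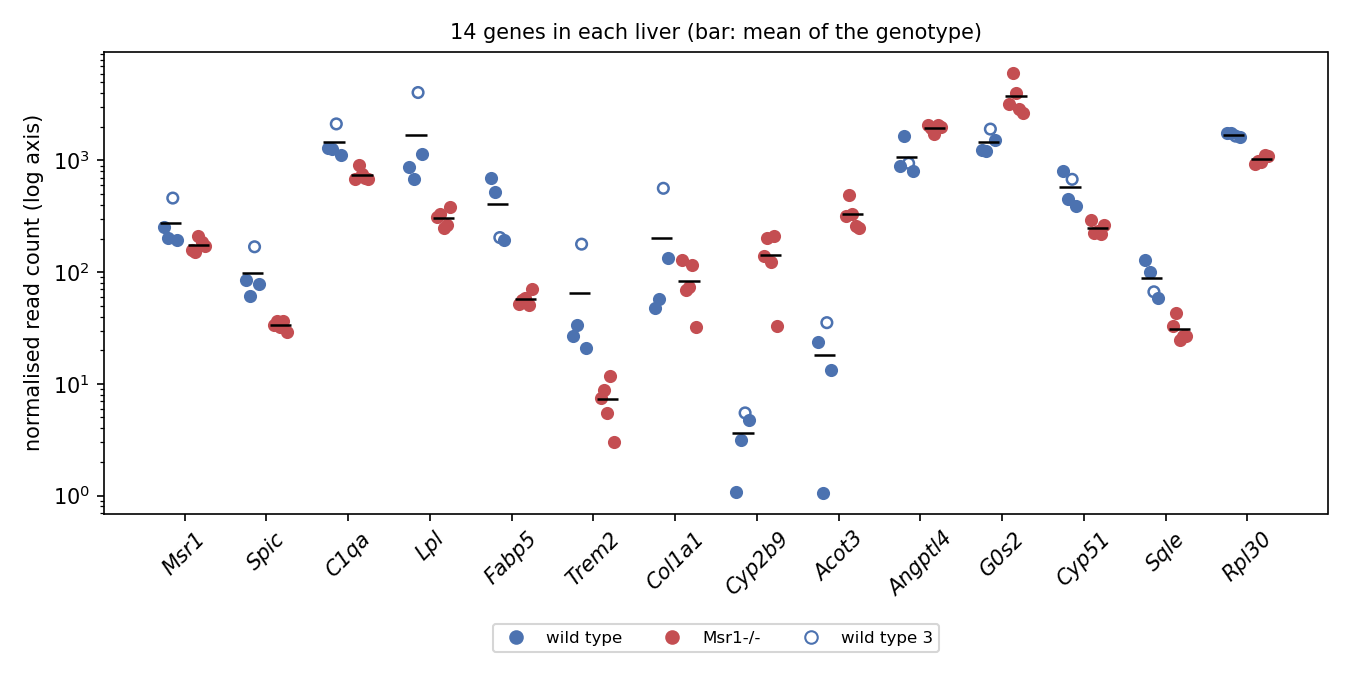
Normalised read counts of 14 genes in each of 9 livers on a log axis, wild type in blue, livers labelled Msr1-/- in red and wild type 3 as an open circle, with a bar at the mean of each genotype. Fabp5 lies lower and Cyp2b9 and Acot3 higher in each of the 5 livers labelled Msr1-/- than in each wild-type liver, and wild type 3 holds the highest Msr1, Spic, C1qa, Lpl, Trem2 and Col1a1.

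Macrophage genes were lower in the livers labelled Msr1-/-. Of 18 Kupffer cell genes, the markers of resident liver macrophages, 17 had a negative log2 fold change (median -0.76, camera adjusted p = 4.18e-11, and adjusted p = 0.202 with an estimated correlation), with 2 past the threshold over all genes and 13 when adjusted over the list alone. Spic, a transcription factor gene of iron-handling macrophages, fell 2.68-fold (from 98.3 ± 48.0 to 33.5 ± 3.1, limma adjusted p = 0.0307), and the complement gene C1qa fell 1.90-fold (from 1455 ± 452 to 748 ± 100, adjusted p = 0.0355). C1qc (1248 ± 479 against 645 ± 76, adjusted p = 0.0575), Clec4f (2155 ± 491 against 1375 ± 138, adjusted p = 0.0766), Marco (702 ± 639 against 170 ± 88, adjusted p = 0.202) and the macrophage marker Adgre1 (299 ± 310 against 94.5 ± 16.9, adjusted p = 0.234) did not pass the limma threshold. The log2 difference of Adgre1 was -1.20, and -0.594 without wild type 3, where wild-type means were 144.2 ± 32.6 for Adgre1 and 405.8 ± 293.4 for Marco. All 18 genes of lipid-associated macrophages had negative log2 fold changes (median -1.21, camera adjusted p = 2.09e-09, and adjusted p = 0.251 with an estimated correlation), with 2 past the threshold over all genes and 8 when adjusted over the list alone. These 2 were Fabp5 and the lipoprotein lipase gene Lpl, which fell 4.23-fold from 1687 ± 1591 to 307.0 ± 53.0. Fabp5 did not follow Trem2 among the wild-type livers, at 204 in wild type 3, which held the highest Trem2, and 697.2, 520.1 and 195.4 in wild type 1, 2 and 4. Wild type 3 held 4057 of Lpl, and without it the wild-type mean was 896.7 ± 230.3 and the fall 2.89-fold (limma adjusted p = 0.00171). Trem2 (64.9 ± 75.7 against 7.3 ± 3.3) and Tyrobp (540 ± 303 against 213 ± 23) had limma adjusted p of 0.064 and 0.0541. Both lists kept the camera call without wild type 3, at a median of -0.62 each. There the limma adjusted p was 0.024 for Trem2, 0.00692 for Tyrobp, 0.0134 for C1qc and 0.0305 for Clec4f. Calls of Spic, C1qa and Lpl did not survive the removal of any 1 liver labelled Msr1-/-, nor of wild type 1, and those of C1qa and Lpl also ended without wild type 2 and wild type 4 respectively, with adjusted p up to 0.0801, 0.0922 and 0.107 over the leave-one-out fits.

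Lists of other immune cells moved the same way. The medians were -1.14 for 10 genes of monocytes and monocyte-derived cells, -1.43 for 3 neutrophil genes, -0.56 for 11 T cell genes and -0.97 for 10 genes of B and plasma cells, with camera adjusted p of 0.000138, 0.000298, 0.00328 and 3.23e-07 (adjusted p = 0.202, 0.202, 0.352 and 0.202 with an estimated correlation). The immunoglobulin light chain gene Igkc fell 3.36-fold, from 398 ± 123 to 118 ± 40 (limma adjusted p = 0.0226), and was the only gene of these 4 lists past the threshold over all genes, while 5, 3, 0 and 6 genes passed when adjusted over the list alone. Its call was kept only without Msr1-/- 2, wild type 3 or wild type 4 (limma adjusted p up to 0.0703). Lyz2 (2186 ± 1859 against 603 ± 133), Cx3cr1 (41.5 ± 46.4 against 6.2 ± 2.1), the neutrophil genes Csf3r (84.2 ± 19.02 against 42.3 ± 7.8) and S100a8 (51.4 ± 26.7 against 11.4 ± 5.2), Ighm (215 ± 60 against 88.9 ± 38.0), Jchain (39.9 ± 9.2 against 19.1 ± 3.5) and Cxcr6 (23.3 ± 9.2 against 10.1 ± 3.2) did not pass. Lyz2 and Cx3cr1 passed without wild type 3, at wild-type means of 1265 ± 313 and 18.4 ± 6.0 (limma adjusted p = 0.0133 and 0.0488), and the log2 difference of Cx3cr1 was then -1.42. Csf3r, Ighm and Jchain also passed without wild type 3 (limma adjusted p = 0.0403, 0.0414 and 0.0145), while S100a8 and Cxcr6 did not. These 4 lists kept the camera call without wild type 3, with medians of -0.52, -1.26, -0.67 and -0.89. The 9 dendritic cell genes had a median of -0.38 (camera adjusted p = 0.00811, and adjusted p = 0.343 with an estimated correlation) with no gene past the threshold over all genes or over the list alone, and Batf3 stood at 27.7 ± 3.2 against 14.6 ± 7.2. That call was lost without wild type 3 (median -0.16, adjusted p = 0.092) and without wild type 1. Of natural killer cell genes only 2 could be tested, too few for the list test, and Klrk1 stood at 46.5 ± 10.7 against 25.7 ± 1.8 (limma adjusted p = 0.0753, and 0.0417 without wild type 3).

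The 15 genes of liver sinusoidal endothelium had a median of -0.01 (camera adjusted p = 0.721), with Mrc1 at 753 ± 94 against 607 ± 96. The 15 genes of hepatic stellate cells, the vitamin A storing cells that can turn into collagen-producing cells, had a median of -0.305 (camera adjusted p = 0.038, and adjusted p = 0.422 with an estimated correlation) and no called gene, with Reln at 619 ± 50 against 499 ± 42 and Pdgfrb at 137 ± 51 against 82.8 ± 19.2. The call was lost without wild type 3 (median -0.10, adjusted p = 0.302), without wild type 4 and without Msr1-/- 1 or 2. Among 4 cholangiocyte genes (median -0.15, camera adjusted p = 0.626), the bile duct transcription factor gene Sox9 fell 2.73-fold, from 77.7 ± 14.2 to 27.7 ± 5.1 (limma adjusted p = 0.0103), while the keratin gene Krt23 stood at 34.5 ± 35.7 against 146.3 ± 55.1 (adjusted p = 0.0755), and 19.1 ± 22.1 in wild type without wild type 3, a 10.4-fold difference (adjusted p = 0.00648). The 7 erythroid genes (median -0.22, camera adjusted p = 0.813) and 6 adipocyte genes (median 0.29, adjusted p = 0.209) were not called as lists. In these, Alas2 stood at 805 ± 215 against 1338 ± 335, and the adipokine gene Cfd rose 9.86-fold, from 24.4 ± 27.4 to 230.7 ± 169.6 (limma adjusted p = 0.0436). The log2 difference of Cfd, 3.30, was 3.93 without wild type 4. The Cfd call was lost without Msr1-/- 1 to 4 or wild type 1 or 2. Pancreas and skeletal muscle markers had 0 and 1 tested genes.

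**Figure D3:**
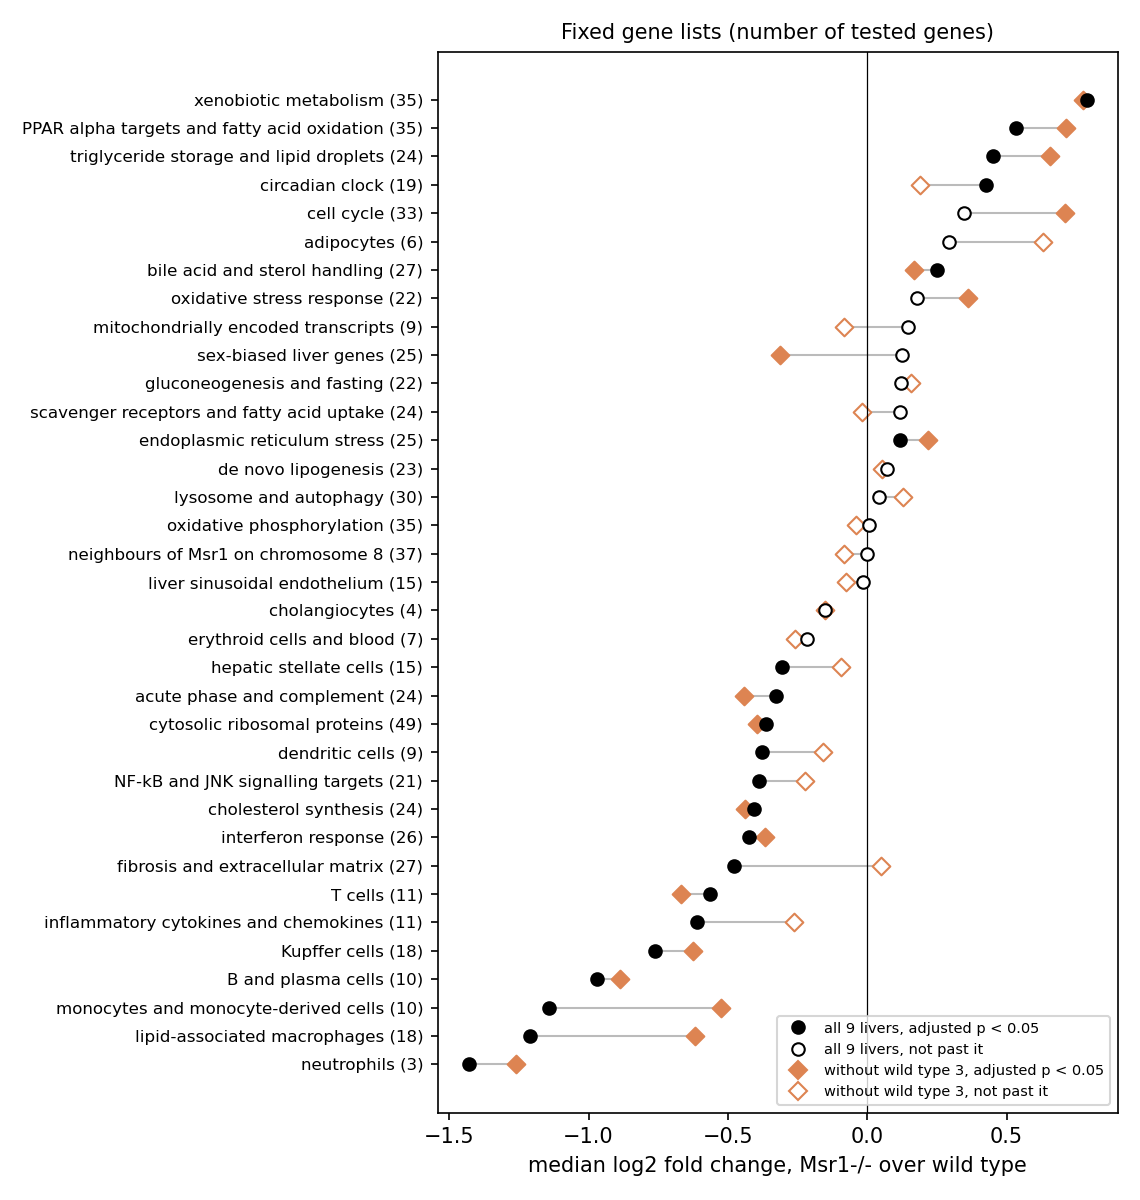
Median log2 fold change (livers labelled Msr1-/- over wild type) of 35 fixed gene lists, with the number of tested genes in brackets, in all 9 livers (circles) and without wild type 3 (diamonds), filled where camera's adjusted p is under 0.05. Kupffer cell genes lie at -0.76 and -0.62, xenobiotic metabolism genes at 0.79 and 0.77, and the fibrosis list moves from -0.48 to 0.05 without wild type 3.

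Inflammatory genes were lower on balance, in part through wild type 3. The 11 tested cytokine and chemokine genes had a median of -0.61 (camera adjusted p = 0.00124, and adjusted p = 0.236 with an estimated correlation), with 3 genes past the threshold when adjusted over the list alone and 1 over all genes, Cxcl14, which fell 2.20-fold from 48.9 ± 17.1 to 20.9 ± 2.7 (limma adjusted p = 0.0489). Of the reruns with 1 liver left out, only that without wild type 3 kept the Cxcl14 call. Cxcl1 (233 ± 49 against 116 ± 31, adjusted p = 0.0525), Il1b (79.0 ± 40.9 against 27.0 ± 11.8, adjusted p = 0.115) and Ccl2 (35.7 ± 48.7 against 11.8 ± 3.5, adjusted p = 0.741) did not pass in limma. The log2 difference of Ccl2 ranged from -1.297 without wild type 2 to 0.166 without wild type 3, where its wild-type mean was 11.5 ± 6.3. Tnf (12.5 ± 11.9 against 4.3 ± 0.9) and Il6 (2.3 ± 0.6 against 0.5 ± 1.1) lay under the mean of 10 and were not tested. Wild type 3 held 29.81 of Tnf, and the other 3 wild-type livers 5.347, 4.22 and 10.44. The 21 targets of NF-kB and JNK signalling had a median of -0.39 (camera adjusted p = 0.00857, and adjusted p = 0.422 with an estimated correlation) and no called gene, with Tnfaip2 at 428 ± 150 against 237 ± 34. Both list calls were lost without wild type 3, at medians of -0.26 and -0.225 and adjusted p of 0.0659 and 0.35. Of 26 interferon response genes, 18 were negative (median -0.43, camera adjusted p = 6.75e-05, and adjusted p = 0.236 with an estimated correlation), none past the threshold over all genes and 4 when adjusted over the list alone. Ifi27l2a stood at 284 ± 153 against 118 ± 27 and Mx1 at 60.0 ± 9.5 against 34.9 ± 6.9.

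Of 24 acute phase and complement genes, 18 were negative (median -0.33, camera adjusted p = 0.00145, and adjusted p = 0.457 with an estimated correlation), with 6 lower and 1 higher when adjusted over the list alone. The serum amyloid genes Saa1 (9646 ± 8151 against 1038 ± 474) and Saa2 (6081 ± 5839 against 456 ± 192) and the lipocalin gene Lcn2 (998 ± 773 against 188 ± 106) spread widely between wild-type livers, with limma adjusted p of 0.0893, 0.109 and 0.0991. Leaving out wild type 4 moved the log2 differences of Saa1 and Saa2 to -3.481 and -3.92, and leaving out wild type 2 moved that of Saa2 to -2.235. The only member past the threshold over all genes went the other way, the serpin gene Serpina3m, which rose 1.80-fold (limma adjusted p = 0.0247). Its call was lost without Msr1-/- 1, 2 or 3 or wild type 2. The 27 fibrosis and extracellular matrix genes had a median of -0.48 (camera adjusted p = 0.0012, and adjusted p = 0.611 with an estimated correlation) with none past the threshold over all genes or over the list alone. Their call was lost without wild type 3 (median 0.05, adjusted p = 0.678). Col1a1 stood at 200.3 ± 244.9 against 83.5 ± 38.8 and, without wild type 3, at 79.3 ± 46.6 in wild type. Values of the smooth muscle actin gene Acta2 were 33.1 ± 29.6 against 19.3 ± 5.9, of Timp2 164 ± 93 against 86.8 ± 5.1 and of Col5a1 111 ± 31 against 74.9 ± 15.9, none of which passed.

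Genes of fatty acid oxidation were higher in the livers labelled Msr1-/-. Of 35 targets of PPAR alpha, the nuclear receptor that drives fatty acid oxidation, 34 had a positive log2 fold change (median 0.53, camera adjusted p = 2.62e-14, and adjusted p = 0.202 with an estimated correlation), with 5 past the threshold over all genes and 16 when adjusted over the list alone. Besides Acot3 and Cyp4a10, these included the thioesterase gene Acot4, which rose 2.58-fold from 107 ± 31 to 274 ± 53 (limma adjusted p = 0.012), and the lipoprotein lipase inhibitor gene Angptl4, which rose 1.90-fold from 1072 ± 387 to 1962 ± 153 (adjusted p = 0.041). The Angptl4 call was kept only without wild type 2 or wild type 3. The median without wild type 3 was 0.71, and 15 genes passed over all genes. Of 24 genes of triglyceride storage and lipid droplets, 20 were positive (median 0.45, camera adjusted p = 0.000278, and adjusted p = 0.422 with an estimated correlation), 4 past the threshold when adjusted over the list alone. G0s2, an inhibitor of lipolysis, rose 2.49-fold from 1470 ± 323 to 3780 ± 1415 (limma adjusted p = 0.0281), a call lost without Msr1-/- 1, 3 or 4 or wild type 1 or 2. Hsd17b11 (3710 ± 466 against 5051 ± 458) and Cideb (390 ± 167 against 613 ± 32) passed only without wild type 3 (adjusted p = 0.0306 and 0.00427). The 23 genes of de novo lipogenesis had a median of 0.07 (camera adjusted p = 0.783) and no called gene, with Pnpla3 at 35.1 ± 20.6 against 12.4 ± 5.0.

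Among 24 genes of scavenger receptors and fatty acid uptake (median 0.12, camera adjusted p = 0.783), the intestinal type fatty acid binding protein gene Fabp2 rose 2.01-fold from 2562 ± 775 to 4978 ± 493 (limma adjusted p = 0.0316), a call kept only without wild type 3. The ferritin receptor gene Scara5 stood at 194 ± 134 against 37.4 ± 21.9 (adjusted p = 0.0595). The fatty acid translocase gene Cd36 stood at 1097 ± 1390 against 1778 ± 945 (adjusted p = 0.417), and without wild type 3, whose value was 3173, at 405 ± 158 in wild type, a 4.04-fold difference (adjusted p = 0.0201). Likewise Pparg stood at 192 ± 163 against 252 ± 76 (adjusted p = 0.529) and passed without wild type 3 (111.3 ± 31.6 in wild type, 2.23-fold, adjusted p = 0.0285). The 22 genes of gluconeogenesis and fasting were not called as a list (median 0.12, camera adjusted p = 0.253), with Asns lower as above and the glucose transporter gene Slc2a2 at 4715 ± 398 against 6116 ± 116. That list passed without Msr1-/- 1.

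The list of cholesterol synthesis genes was lower in the livers labelled Msr1-/-. Of 24 genes, 20 were negative (median -0.405, camera adjusted p = 9.43e-07, and adjusted p = 0.202 with an estimated correlation), with 2 past the threshold over all genes and 3 when adjusted over the list alone. The lanosterol demethylase gene Cyp51 fell 2.26-fold from 582 ± 193 to 248 ± 30 (limma adjusted p = 0.0247) and the squalene epoxidase gene Sqle 2.72-fold from 88.2 ± 31.6 to 30.9 ± 7.4 (adjusted p = 0.0281). Both calls were lost without any 1 of the livers labelled Msr1-/- or wild type 1, and that of Sqle without wild type 2. Dhcr7 (503 ± 51 against 301 ± 82, adjusted p = 0.0675) did not pass. Of 27 genes of bile acid and sterol handling, 21 were positive (median 0.25, camera adjusted p = 0.0012, and adjusted p = 0.236 with an estimated correlation), with 2 past the threshold when adjusted over the list alone. The bile acid efflux transporter gene Abcc3 rose 2.23-fold from 1708 ± 732 to 3579 ± 469 (limma adjusted p = 0.0498), a call kept only without wild type 3. The sterol transporter genes Abcg5 (2944 ± 1513 against 4844 ± 993) and Abcg8 (2224 ± 830 against 3898 ± 748) had adjusted p of 0.195 and 0.0967. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 3087 ± 2750 against 2272 ± 1837 (adjusted p = 0.846).

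The list of xenobiotic metabolism genes was higher. Of 35 genes, 32 were positive (median 0.79, camera adjusted p = 1.5e-10, and adjusted p = 0.0154 with an estimated correlation), the only list that passed in both forms of the test. Over all genes 5 passed and over the list alone 9, among them Cyp2b9, Cyp2c29, the bilirubin glucuronosyltransferase gene Ugt1a1 (2.79-fold higher, limma adjusted p = 0.0347) and the carboxylesterase gene Ces1d (1.95-fold higher, adjusted p = 0.041). Ugt1a1 kept its call only without Msr1-/- 4 or wild type 3, and Ces1d only without wild type 1 or 3. The adjusted p with an estimated correlation was 0.0978 without wild type 3. Of the 25 sex-biased liver genes, 13 were positive and 12 negative (median 0.12, camera adjusted p = 0.813). The list mixes male-biased and female-biased genes, so its median and camera's p cannot show a shift towards either pattern. Past the threshold over all genes were the female-biased Cyp2b9, Hao2 and Acot3, all higher, and the male-biased Moxd1, lower. For changes in either direction, fry gave an unadjusted p of 0.000149. The median of the list without wild type 3 was -0.31 (camera adjusted p = 0.0206, and adjusted p = 0.488 with an estimated correlation), with 4 higher and 8 lower past the threshold over all genes.

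All 49 tested genes of cytosolic ribosomal proteins had negative log2 fold changes (median -0.365, camera adjusted p = 6.6e-23, and adjusted p = 0.202 with an estimated correlation), with 4 past the threshold over all genes and 28 when adjusted over the list alone. Rpl30 fell 1.66-fold from 1696 ± 80 to 1026 ± 81, Rps24 1.53-fold, Rpl22 1.39-fold and Rpl23 1.43-fold (limma adjusted p = 0.00984, 0.0221, 0.0386 and 0.041). Rps24 lost its call without Msr1-/- 1, 2, 3 or 5 or wild type 2, and Rpl22 and Rpl23 kept theirs only without wild type 3. The median was -0.40 without wild type 3, and 16 genes passed over all genes. Of 25 endoplasmic reticulum stress genes, 19 were positive (median 0.12, camera adjusted p = 0.0354, and adjusted p = 0.399 with an estimated correlation), with none past the threshold over all genes and 4 higher and 1 lower when adjusted over the list alone. Herpud1 (3233 ± 545 against 5073 ± 588) and Pdia4 (2202 ± 411 against 3272 ± 471) were the larger, and Xbp1, which encodes a transcription factor of this response, the smaller (3775 ± 588 against 2745 ± 285). The call was lost without Msr1-/- 1, 2, 4 or 5 and without wild type 2 or 4, with adjusted p up to 0.168. The 19 circadian clock genes had a median of 0.425 (camera adjusted p = 0.00811, and adjusted p = 0.399 with an estimated correlation) and no called gene. The clock gene Hlf stood at 676 ± 275 against 903 ± 69 (limma adjusted p = 0.398). The list call was lost without wild type 3 (median 0.19, adjusted p = 0.35).

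The 22 oxidative stress genes (median 0.18, camera adjusted p = 0.051) and the 33 cell cycle genes (median 0.35, adjusted p = 0.0504) narrowly missed the threshold, and both passed without wild type 3 (medians 0.36 and 0.71, adjusted p = 4.21e-06 and 2.32e-09, and adjusted p = 0.23 and 0.24 with an estimated correlation) and without Msr1-/- 4 or 5. The epoxide hydrolase gene Ephx1 stood at 5777 ± 2029 against 10460 ± 1861, Aox1 at 1480 ± 243 against 2552 ± 706, Cdk1 at 55.8 ± 48.0 against 79.3 ± 23.7 and Rrm2 at 110.4 ± 14.6 against 149 ± 21. Ccnd1 stood at 454 ± 685 in wild type, with 1479 in wild type 3, against 76.3 ± 10.7. Its log2 difference ranged from -2.009 without wild type 2 to -0.395 without wild type 3, where the wild-type mean was 112.2 ± 61.0. Cdk1 then stood at 32.0 ± 8.2 in wild type and passed (limma adjusted p = 0.017). The 30 lysosome and autophagy genes (median 0.04, camera adjusted p = 0.783), 35 oxidative phosphorylation genes (median 0.0046, adjusted p = 0.92) and 9 mitochondrially encoded transcripts (median 0.15, adjusted p = 0.788) were not called, with Ctsc at 1242 ± 290 against 738 ± 79 and Ndufv1 at 1623 ± 107 against 1924 ± 94. Nnt, whose loss marks some C57BL/6 substrains, was read in both genotypes, at 680 ± 211 against 807 ± 90 (limma adjusted p = 0.507). Gene totals do not show which exons these reads came from, so they do not tell whether the substrains differ. Nnt passed without wild type 3, whose value was 996.3 (1.40-fold higher, adjusted p = 0.036).

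Of 37 tested genes around Msr1 on chromosome 8, 18 were positive and 19 negative (median -0.0014, camera adjusted p = 0.608). The phosphatase gene Mtmr7 (40551095 to 40634797 in mm10) rose 3.27-fold from 52.1 ± 8.1 to 176.3 ± 48.8, and Fgl1 (41191434 to 41215156) fell from 11990 ± 9989 to 1292 ± 275. Acsl1 (10400 ± 2370 against 17520 ± 2110, limma adjusted p = 0.0618) and Mtus1 (1895 ± 125 against 2384 ± 109, adjusted p = 0.112) did not pass. Chromosome 8 held 23 called genes among 701 tested (3.28%), against 1.26% of tested genes on the other chromosomes. Within 35 Mb of Msr1, 19 of 308 genes were called, 6 higher and 13 lower, and Zfp868 (69610857 to 69625548), Hapln4 (70083457 to 70090862) and Lpl (68880491 to 68907448) were among them.

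**Figure D4:**
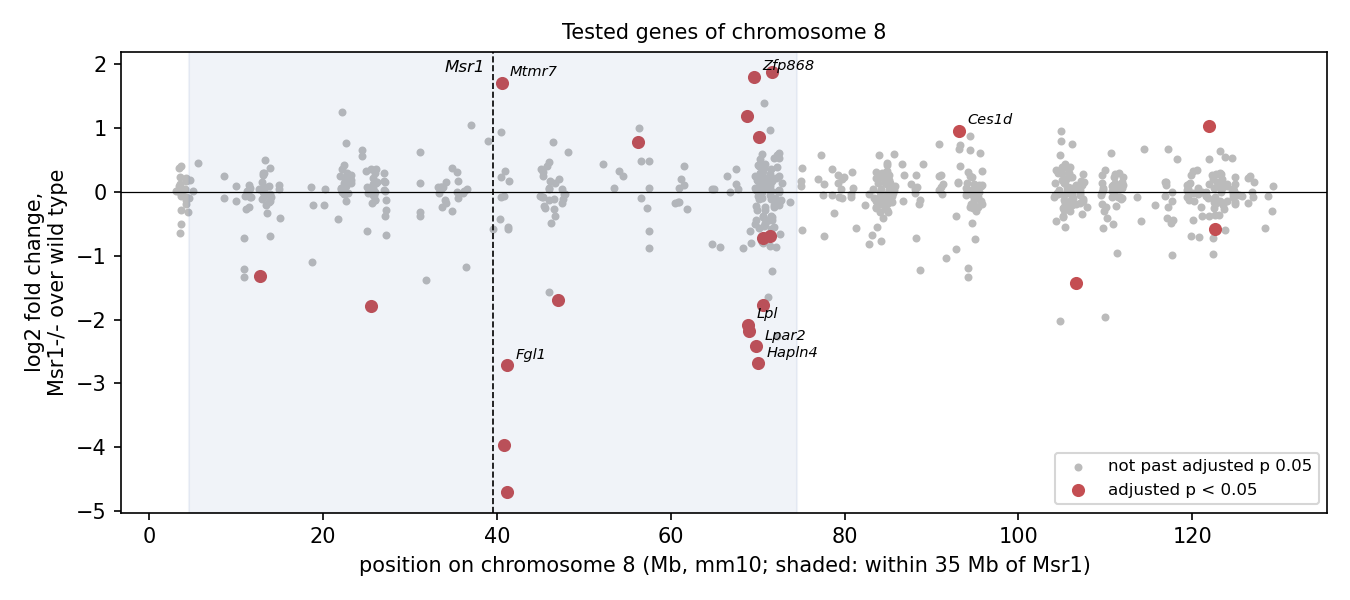
Log2 fold change (livers labelled Msr1-/- over wild type) of the 701 tested genes of chromosome 8 by position in Mb, with called genes in red, Msr1 at the dashed line and the shaded part within 35 Mb of it. Of 23 called genes, 19 lie in the shaded part, several of them near 41 Mb and near 70 Mb.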

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

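Of the explanations weighed here, the tests of read depth and of an exchanged genotype label for wild type 3, of chance placement and of a strain segment on chromosome 8 were chosen after the results were seen, and the others before. Testing each of 312 groups of values for a liver far from the others of its genotype gave 16 such livers (5.13%), and chance alone gives about 1 in 20. In wild type 3 the normalised read counts of Lrtm1 (5.491) and Igkc (216.5) lay far below those of the other wild-type livers, and those of Ifi27l2a (512.3), Nnt (996.3), Fcer1g (714.7), Ncf1 (184.4) and Pirb (181.2) far above. Wild type 4 had the highest Tpm2 (320.7) and Cfd (65.46), and wild type 1 the lowest Reln (544.3). In Msr1-/- 5, Cyp2b9 (33.06), Cyp4a10 (2386), Mtus1 (2198) and the mean log2 value of the xenobiotic metabolism list (11.19) were lowest by a wide gap. In Msr1-/- 2, Il1b (47.95) and the mean log2 value of the NF-kB and JNK list (7.002) were highest. Of 100 splits of the 9 livers into 5 and 4, only the real one, 1 split, called as many as 177 genes in limma, and the highest of the others called 5. Without wild type 3, again 1 of the 56 splits, the real one, reached 629 genes, and the highest other called 1. Chance does not give either count.

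Wild type 3 carried more macrophage signal than the other 3 wild-type livers, while its read total, 16.99 M, lay inside the range of the others, which argues against depth. A lower share of hepatocyte RNA would raise all other cell types alike, but the medians of 8 lists against the other wild-type livers ran from -0.16 for T cells to 2.09 for lipid-associated macrophages, a spread of 2.25 (permutation p = 0.00024). That p compares only the highest and lowest list, picked as such, and treats genes of a single liver as independent. It therefore does not test the spread over the 8 lists. Of 49 genes that separate the other 8 livers by more than 1 log2, 29 lay nearer wild type (59.2%, exact 95% interval 44.2 to 73), which alone left an Msr1-/- liver labelled wild type undecided, and 9 of the 10 on chromosome 8 did (90%, interval 55.5 to 99.7), a subset picked after the 49 were seen. The third test tried for this explanation used 4 genes, likewise picked after their values were seen. Wild type 3 lay at least 7.53 SDs off the mean of the livers labelled Msr1-/- in each. These were Zfp868 (93.35 against 297.8 to 374.4 in livers labelled Msr1-/-), Hapln4, Lpar2 and Gm20305 (0 against 104.9 to 127.2). In all 4 genes wild type 3 was already seen to lie with the other wild-type livers. The choice of genes thus set the outcome, and the test does not exclude a liver of the same line as the other 5. A mislabelling stays open, since wild type 3 lay nearer wild type in 63.5% (interval 49 to 76.4) of the 52 chromosome 8 genes called without it. The intervals given here treat genes of a single liver as independent, so they do not measure the uncertainty about this animal. A liver with more advanced disease, which no label records, also stays open.

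Called genes lay on chromosome 8 more often than elsewhere, 23 of 701 against 1.26%. Chance placement gives as many with an exact one-sided p of 8.9e-05, and without wild type 3 an excess remained, though smaller (52 of 698 genes, 7.45%, against 4.75% elsewhere, exact p = 0.0016), so neither is the whole cause. A candidate explanation is a segment from another strain carried along with the targeted Msr1 allele: the share of called genes within 35 Mb of Msr1 was 6.06 times that on the rest of the chromosome (19 of 308 against 4 of 393, Fisher's exact one-sided p = 0.000134), and 2.88 times without wild type 3 (36 of 306 against 16 of 392, p = 0.000112). Of the chromosome 8 genes not called, 20.4% within 35 Mb and 12.3% on the rest had an unadjusted limma p under 0.05 (Fisher's exact one-sided p = 0.00314). Without wild type 3 these shares were 22.6% and 18.4% (Fisher's exact one-sided p = 0.11). Strain variants within a segment from another strain may change both expression and read alignment, and an effect of Msr1 loss itself on these genes also stays open. With chromosome 8 left out, 73 genes were called higher and 70 lower, and 21 lists were called. That rerun covers chromosome 8 only, and strain differences on other chromosomes were not tested.

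The negative log2 fold changes of all 49 ribosomal protein genes (median -0.365) were set against technical trends. Length and GC content were those of the longest annotated transcript of each gene, which need not be the one sequenced. With a smooth trend of fold change on this length removed, the median was -0.313, and with a trend on GC content removed it was -0.34. Each had a permutation p of 1e-04, the smallest that 10000 random lists can give, but genes of random lists do not move together as these may. Trends on the transcripts sequenced were not tested, so bias by length or GC content stays open. Under TMM scaling the median was -0.37 and under quantile scaling -0.445, so the size factors do not account for it. The genotype as labelled stays open as a cause, as does a shared response of these genes, which are strongly co-regulated: with an estimated correlation the list's adjusted p was 0.202.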

How the results depend on the processing

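The alternatives without wild type 3 by edgeR or DESeq2 and without chromosome 8 were chosen after seeing the data. The counts of 86 higher and 91 lower genes stayed within 1.5 times under other pseudocounts, no filter, TMM, quantile scaling, edgeR and chromosome 8 left out. A mean of 50 or more left 58 lower, from fewer genes tested. DESeq2 called 307 higher and 466 lower (176 of the 177 shared), array weights 277 and 254, edgeR without wild type 3 304 and 352, and DESeq2 without it 539 and 520; the cause was not tested. Leaving out single livers gave 19 to 332 higher, 17 to 297 lower and 18 to 22 lists. With the animal number as a replicate block, limma called 8 higher and 0 lower (833 lower at an unadjusted p under 0.05; edgeR 111 and DESeq2 466 without the block) and 24 lists. Same-numbered animals deviated with correlations of 0.025, -0.077, -0.1 and 0.22. Animals of different numbers were not compared, so whether the numbers pair the livers stays open. Of 21 lists, 1 passed with an estimated correlation and 8 with fry. The Msr1 difference was -0.581 under quantile scaling (exact p = 0.0635), from -0.719 to -0.306 on leaving out single livers (exact p up to 0.107), and kept its call under both pseudocounts, TMM and linear values. The median of the sex-biased list turned from 0.12 to -0.312 without wild type 3 (-0.312 to 0.183 over single livers left out), -0.273 there with edgeR and -0.267 with DESeq2. That list mixes male-biased and female-biased genes, so the sign of its median gives no direction of sex bias. The fibrosis list, called at -0.478, turned to 0.0478 without wild type 3 and was not called there. The oxidative phosphorylation list passed only under quantile scaling, with its median turned negative. Other called genes and lists kept their direction, with 9 sign changes among genes and 33 among lists that passed in neither fit. Depth limits low genes such as Tnf and Il6.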

Other observations

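The genes in this part were chosen after their values were seen, outside the rule for named genes. Of genes with roles in myeloid cells that are on none of the fixed lists, 6 picked by hand, with no test as a group, were lower in the livers labelled Msr1-/- (n = 5) than in wild type (n = 4). Fcer1g, a signalling chain of antibody receptors, fell 2.04-fold (480 ± 157 to 229 ± 34, limma adjusted p = 0.0316), and Ncf1, a subunit of the phagocyte oxidase, fell 2.38-fold (115 ± 47 to 45.5 ± 5.2, adjusted p = 0.0291). The inhibitory receptor gene Pirb fell 2.08-fold, the leukocyte integrin gene Itgal 1.88-fold, the properdin gene Cfp 1.86-fold and the perforin-like gene Mpeg1 2.20-fold. Without wild type 3, in which Fcer1g, Ncf1 and Pirb were highest, all 6 stayed past the threshold, with limma adjusted p of 0.00904, 0.00788, 0.0201, 0.0179, 0.00753 and 0.0229. Each of these calls was lost on leaving out some single liver. Cfp lost its call without Msr1-/- 1 or 2, and Pirb kept its call only without wild type 3. Fcer1g, Ncf1, Itgal and Mpeg1 lost theirs without any 1 of the livers labelled Msr1-/- or wild type 1 or 2. The highest adjusted p over single livers left out was 0.113, for Mpeg1.

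Of genes of retinoid metabolism, 3 were higher in the livers labelled Msr1-/-. The retinaldehyde dehydrogenase gene Aldh1a1 rose 1.85-fold (17920 ± 4276 to 32670 ± 4023, limma adjusted p = 0.0433), the retinol saturase gene Retsat 1.66-fold and the retinol dehydrogenase gene Rdh16 2.20-fold. Aldh1a1 kept its call only without wild type 1 or 3 (limma adjusted p up to 0.117). Retsat lost its call without Msr1-/- 1, 2, 4 or 5 or wild type 1 or 2, and Rdh16 without Msr1-/- 1 to 4 or wild type 1 or 2.

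Gm20305 on chromosome 1 had no read in the 4 wild-type livers and 118.3 ± 8.8 in the livers labelled Msr1-/-, at least 40.9-fold higher against the floor of 3 reads per liver (limma adjusted p = 1.43e-07), and it was called with each liver left out. The Y-linked gene Ddx3y stood at 624 ± 127 in wild type and 637 ± 78 in livers labelled Msr1-/-, and Xist at 2.7 ± 2.9 and 0.6 ± 1.3, as male animals give.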
